A study of Mus musculus with 6 samples.

How the data were processed

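RNA was measured in 6 libraries of mouse intestinal epithelial cells in 3 groups of 2: cells with 1 Neurog3 allele and an EGFP reporter, cells with 2 alleles and an EYFP reporter, and wild-type epithelium. Per the labels' protocols, total RNA was extracted with the RNeasy Micro kit, libraries were made with the Illumina TruSeq RNA kit and sequenced on a HiSeq2000 as single-end reads of 50 bases. Per the series' design text, Neurog3-expressing cells were isolated by flow sorting. The gut segment of the sorted cells, the gates and whether the wild-type cells were sorted are not given in the sources used here, and the titles of the wild-type libraries point to duodenum. Per the submitters' processing notes, FastQC 0.11.8, Bowtie2, RSEM 1.3.1, DESeq2 1.26.0 and the mm10 genome build were used. The roles and settings of these tools, the version of Bowtie2 and the strand setting are not given in the sources used here.

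The authors deposited a table of estimated counts per gene, which need not be whole numbers because reads that match several genes are divided between them. The authors' deposited table of comparisons holds a signal per library, which equals the whole part of the count divided by 1 size factor per library. It also holds a linear fold per comparison, which the authors' deposited columns give with the second-named group over the first, as tested against the signal columns. The adjusted p-value per comparison in the authors' deposited table is used only as the authors give it. Of its gene names, 23 look like dates, as a spreadsheet makes from gene symbols, and have no match in the count table; 14 folds are missing for EGFP cells against wild type. In both tables the columns of the EYFP libraries carry EGFP in their names together with the word addon, and were matched to the samples whose titles hold that word. Gene symbols are those of the count table. Of its 23845 genes, 23580 (98.9%) matched a RefSeq accession of the mm10 assembly, from which coordinates were taken; 375 of the 378 list symbols had a row, among them Clca1 as Clca3 and Jchain as Igj.

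Total counts per library ranged from 7938358 to 20589683, so that a gene at 1 CPM rests on few reads in the smallest library, and the ribosomal RNA gene Rn45s took 0.18% to 1.93% of the counts. Estimated counts were rounded to whole numbers. Genes with low counts were removed with edgeR's filterByExpr, which left 13935 genes (58.4%). Counts were scaled with TMM factors and tested with edgeR's quasi-likelihood F test (robust fit) in 1 model of 3 group means over all 6 libraries, with 3 residual degrees of freedom and Benjamini-Hochberg adjustment at 0.05. The biological coefficient of variation was 19.8%. The SE of a log2 fold change was derived from its F value. Values in CPM are counts over the library total multiplied by its TMM factor. A group whose libraries were all at 0 was given a floor of 3 counts over the group, and a group with 1 to 3 counts a ratio of levels with an exact 95% interval (Clopper-Pearson, on the division of the counts between the groups); both cover counting error only. Without 1 library, the floor and the interval apply to the libraries that are left.

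Gene lists were tested with camera in limma, with a preset correlation between genes of 0.01, on log2 CPM with a prior count of 2, adjusted over the 20 lists of a comparison. Camera with an estimated correlation and fry were alternatives. The former estimates the correlation from 3 residual degrees of freedom and called no list in any comparison, so its adjusted p does not separate the lists. Fry tests whether the genes of a list move one way and does not compare them with other genes. There were 10 lists for the cell types and states the study concerns and 10 for other cell types, gut regions and stress states that a sort could hold. The test, the lists, the alternatives and the rule for named genes were chosen before the data were examined. The rule named Neurog3, the first symbol of each of the first 10 lists, and the member or members of each list with the largest change past the test. Those were 2 members for the first 10 lists between EYFP and EGFP cells, and 1 member otherwise. It also named the 3 genes higher and 3 lower with the largest change outside the lists, at 10 CPM or more in both libraries of the higher group and with a symbol that is not of the Gm, Rik or ENSMUSG kind. Other members named, such as Neurod1, Gip, Sst, Tph1, Ddc, Dll1, Hes6, Dll4, Cbfa2t3 and B2m and those that spell out a small count, were chosen after their values were seen.

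The alternatives were DESeq2 size factors, scaling without the 50 most abundant genes, no filter on low counts, a minimum of 10 counts in both libraries of a group, the DESeq2 Wald test, a fit to only the 4 libraries compared, the replicate number as a block, a fold of at least 2, and leaving out each library in turn. Where a group was left with 1 library, that library was assumed to vary like the others. Tests on autosomal genes alone and against a fold of 2 were added after seeing the data.

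Replicates differed by more than sampling noise, with a chi-square per degree of freedom of 28 for EGFP, 30.4 for EYFP and 78 for wild type, and correlated across genes at a Spearman rho of 0.982, 0.984 and 0.981. The labels do not say that replicates came from separate animals, so p-values measure the spread between these samples. The wild-type replicates differ in sex-linked transcripts and so were not repeats of 1 sample; in the other groups the spread may be technical. The procedure was tested on simulated counts of the 13935 genes for EYFP against EGFP cells. It recovered 44 of 100 genes changed 2-fold and 79 of 100 changed 4-fold, with 6 false calls among 129. The simulation changed 100 genes by each fold, balanced between rises and falls, while 5045 genes were called in the data. Recovery and scaling were therefore not tested where so many genes change. A shifted list had an adjusted p of 4.5e-53 in camera, and 0 of 19 random lists were called. The simulated genes were drawn independently of each other, while the estimated correlation within the lists reached 0.74, for cell cycle genes. The simulation therefore does not test camera on lists whose genes vary together. Analyses used R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and figures were drawn with Python 3.11.15 and matplotlib 3.10.9.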

Results

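Transcriptomes were profiled in 6 RNA-seq libraries of mouse intestinal epithelial cells, 2 per group. The first group held cells sorted for a fluorescent Neurog3 reporter from mice whose labels give 1 Neurog3 allele and EGFP (EGFP cells). The second held cells sorted for an EYFP reporter from mice with 2 Neurog3 alleles (EYFP cells). The third was wild-type intestinal epithelium, which the labels do not describe as sorted for a reporter. Neurog3 is the transcription factor that commits intestinal progenitors to the enteroendocrine lineage, the hormone-secreting cells of the gut. The series asks how the dose of this gene affects the differentiation of these progenitors. The labels give the strain of the EGFP and wild-type libraries as C57BL6 and that of the EYFP libraries as a mix of C57BL6 and CD1. Total estimated counts were 7938358 and 11714961 in the EGFP libraries, 12415664 and 10173137 in the EYFP libraries, and 13674214 and 20589683 in the wild-type libraries. Of 23845 genes in the count table, 13935 were tested. Values below are counts scaled to the TMM-adjusted library total (CPM), means are given with their SD (n = 2), and log2 fold changes with their standard error (SE). Adjusted p of single genes are from edgeR's quasi-likelihood test and those of gene lists from camera.

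Neurog3 itself, on chromosome 10 from 62133090 to 62134763 in mm10, was measured first. It stood at 120 and 179 CPM in the EGFP libraries, 563 and 348 CPM in the EYFP libraries, and 6.0 and 6.39 CPM in wild-type epithelium. EYFP cells held 3.05-fold more Neurog3 transcript than EGFP cells (log2 fold change 1.61 ± 0.28, edgeR adjusted p = 0.0049). The groups also differed in sex-linked transcripts. Xist, which is transcribed from the inactive X chromosome of females, stood at 966 and 969 CPM in the EGFP libraries and at 0.634 and 2.36 CPM in the EYFP libraries. In wild type it stood at 1.17 CPM in replicate 1 and 726 CPM in replicate 2. The Y-linked gene Ddx3y was at 0 in both EGFP libraries, at 37.3 and 39.3 CPM in EYFP, and at 62.4 and 0.121 CPM in wild type. Strain, reporter and these sex-linked transcripts therefore differ together between EGFP and EYFP cells, for every gene group below.

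The comparison of EYFP with EGFP cells sets 2 Neurog3 alleles beside 1, together with the differences in strain, reporter and sex-linked transcripts. Transcription factors of the enteroendocrine lineage rose as a group in EYFP cells: 24 of the 26 measured were higher, 0 were lower and 2 did not pass, with 25 higher when adjusted over the list alone. The median log2 fold change of the list was 1.89 (camera adjusted p = 6.8e-14, but adjusted p = 0.37 with an estimated correlation). Mnx1, a homeobox factor, went from 11 ± 0.63 to 71.1 ± 37.4 CPM (log2 fold change 2.69 ± 0.39, edgeR adjusted p = 0.0031; 2.02 without EYFP replicate 1). Neurod1, a direct target of Neurog3, reached 545 and 488 CPM in EYFP against 112 and 149 CPM in EGFP. The early growth response factor Egr4 was 3.13 ± 0.80 higher on the log2 scale, at 8.91 ± 2.03 CPM in EYFP (4.74 without EGFP replicate 1), but its call was lost without EGFP replicate 2 (2.29, adjusted p = 0.075), EYFP replicate 1 (0.056) or EYFP replicate 2 (0.085). Genes of the secretory granule and of exocytosis rose with them, with 20 of 25 higher, 0 lower and 5 not past the test (23 higher when adjusted over the list alone). Their median was 1.64 (camera adjusted p = 5.4e-11, but adjusted p = 0.37 with an estimated correlation). Chromogranin A (Chga), a core protein of these granules, rose from 2673 ± 967 to 10120 ± 719 CPM (log2 fold change 1.92 ± 0.32). Rab3c, a small GTPase of secretory vesicles, and Pcsk1n, an inhibitor of prohormone convertase, rose by 2.95 ± 0.33 and 2.43 ± 0.19 on the log2 scale.

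Of the 16 measured hormone and serotonin synthesis genes, 5 were higher in EYFP cells, 0 were lower and 11 did not pass, with 5 higher when adjusted over the list alone. The list median was 1.16 (camera adjusted p = 0.0018, but adjusted p = 0.49 with an estimated correlation), and without EYFP replicate 2 the adjusted p was 0.066. Tac1, the precursor of substance P, rose from 355 ± 5.36 to 1935 ± 782 CPM (log2 fold change 2.45 ± 0.29), and Ucn3, urocortin 3, by 2.06 ± 0.39 (2.83 without EGFP replicate 2). Gcg, the precursor of glucagon and GLP-1, was 1.78 ± 0.33 higher (edgeR adjusted p = 0.0056), a call lost without EGFP replicate 1 (log2 fold change 1.55, adjusted p = 0.06). Tph1 and Ddc were the other hormone-list genes that rose, by 1.96 and 1.95 on the log2 scale. Tph1 carries out the first step of serotonin synthesis in enterochromaffin cells, and Ddc the step after it. The EYFP libraries differed from each other for several hormones. Gip stood at 2039 and 11598 CPM in EYFP against 4456 and 5704 CPM in EGFP, and Sst at 695 and 2124 CPM against 840 and 710 CPM. Genes of enterochromaffin cells, a list that shares members with the endocrine lists, had 9 of 12 members higher and 1 lower, Gpr35. With 10 higher and 1 lower when adjusted over the list alone, its median was 1.96 (camera adjusted p = 9.9e-05, but adjusted p = 0.42 with an estimated correlation).

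Markers of the other secretory lineages fell in EYFP cells. Of 30 goblet cell markers, 28 were lower, 0 were higher and 2 did not pass (29 lower when adjusted over the list alone). The median log2 fold change was -5.04 (camera adjusted p = 8.4e-20, but adjusted p = 0.37 with an estimated correlation). Muc2, the main mucin of intestinal mucus, stood at 4661 ± 683 CPM in EGFP and 25 ± 24.1 CPM in EYFP (log2 fold change -7.55 ± 0.90, edgeR adjusted p = 0.0021). Zg16, a lectin of the mucus, stood at 13220 ± 7163 against 57.4 ± 55.2 CPM. The chloride channel regulator Clca1, whose row in the file is named Clca3, had a log2 fold change of -7.66 ± 1.35; it belongs to a family of similar genes, and its adjusted p was 0.051 without EGFP replicate 2. Of 20 Paneth cell markers, 17 were lower and 0 higher, with 18 lower when adjusted over the list alone. Their median was -4.71 (camera adjusted p = 5.1e-12, but adjusted p = 0.37 with an estimated correlation). Lysozyme 1 (Lyz1) stood at 3887 ± 896 CPM in EGFP and 200 ± 108 CPM in EYFP (log2 fold change -4.28 ± 0.45), and Pla2g2a, a secreted phospholipase, fell by 7.04 ± 0.41. The values of Mptx2 (log2 fold change -6.70 ± 0.81), of Lyz1 and of the Defa genes are uncertain, since reads shared among near-identical copies are divided between them by the estimation. Tuft cell markers fell in 13 of 17 cases with 0 higher (15 lower when adjusted over the list alone). The median was -4.32, or -3.72 with Gng13 at its bound (camera adjusted p = 1.3e-06, but adjusted p = 0.42 with an estimated correlation). Pou2f3, the transcription factor that specifies tuft cells, fell by 5.68 ± 0.60. Dclk1, a kinase used as their marker, had a log2 fold change of -4.53 ± 0.86. Its adjusted p was 0.079 without EYFP replicate 1 and 0.056 without EYFP replicate 2. Gng13, a G protein subunit, had 0 counts in both EYFP libraries and was at least 11.7-fold lower there, from a floor of 3 counts over the group; its adjusted p was 0.06 without EGFP replicate 1, and the bound was 5.32 and 6.35 without EYFP replicates 1 and 2. The size of these falls depended on the EYFP library. Without EYFP replicates 1 and 2, the log2 fold change was -6.79 and -9.2 for Muc2, -7.1 and -9.49 for Zg16, -6.86 and -9.61 for Clca1, and -6.09 and -7.62 for Mptx2. It was -4.97 for Lyz1 without EYFP replicate 1, -5.2 for Dclk1 without EYFP replicate 2 and -7.15 for Zg16 without EGFP replicate 2.

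**Figure D1:**
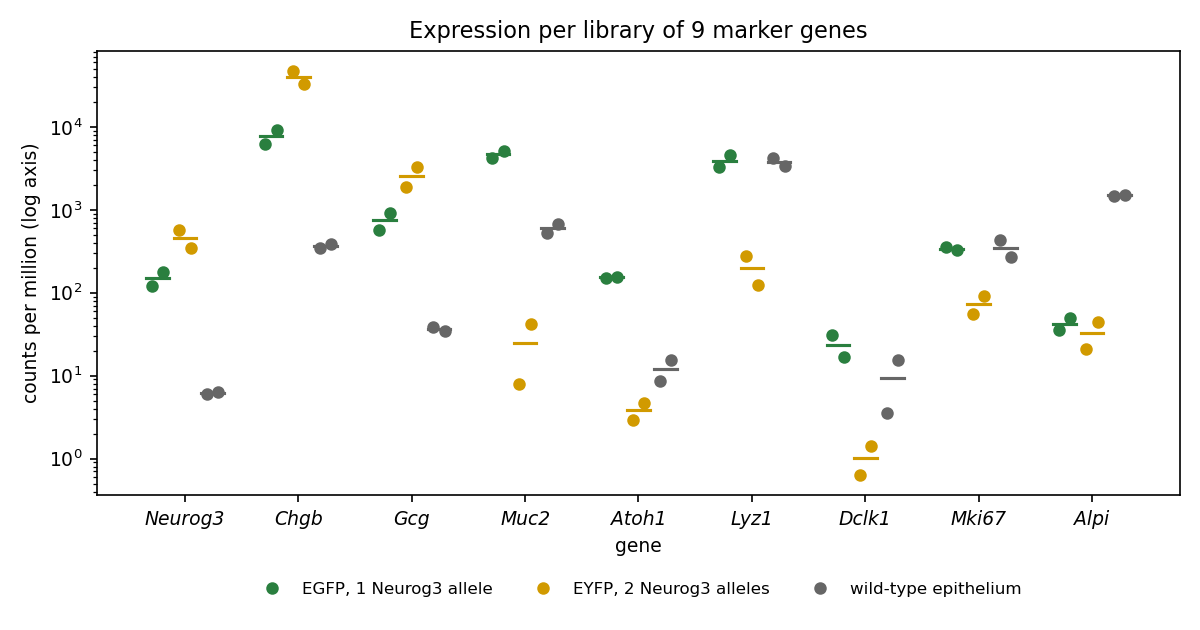
CPM on a log axis for 9 genes, with 1 point per library, colours for the 3 groups and a bar at the group mean. Muc2 stands at 4179 and 5144 CPM in the EGFP libraries against 7.96 and 42.1 CPM in the EYFP libraries, while Chgb is higher in EYFP, and Alpi lies far below wild type in both sorted groups.

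Genes of secretory progenitors and the Notch pathway went in both directions. Of 18 measured, 4 were higher, 7 lower and 7 did not pass (5 higher and 7 lower when adjusted over the list alone), and camera gave an adjusted p of 0.43 for a median of -0.03. Atoh1, the transcription factor required for all secretory lineages, stood at 153 ± 3.27 CPM in EGFP and 3.83 ± 1.24 CPM in EYFP (log2 fold change -5.32 ± 0.35, edgeR adjusted p = 0.00023). Gfi1, which acts downstream of Atoh1, fell by 6.85 ± 0.43, and the Notch ligand gene Dll1 fell by 2.31 on the log2 scale. The members that rose were Maml3, Mfng, Tubb3 and Hey1, where Tubb3 is a neuronal tubulin and Mfng a glycosyltransferase that modifies Notch. Hes6, Dll4 and Cbfa2t3 did not pass, with log2 fold changes of -0.01, 0.23 and -0.05.

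All 30 cell cycle genes were lower in EYFP cells, by the all-gene adjustment and when adjusted over the list alone. The median log2 fold change was -2.11 (camera adjusted p = 7.3e-17, but adjusted p = 0.37 with an estimated correlation). Mki67, a marker of dividing cells, stood at 340 ± 16.1 CPM in EGFP and 73.2 ± 25 CPM in EYFP. The mitotic kinase Plk1 fell by 3.27 ± 0.26 and the ribonucleotide reductase subunit Rrm2 by 2.79 ± 0.27. Of 22 intestinal stem cell genes, 8 were lower, 1 (Cd44) was higher and 13 did not pass; adjusted over the list alone, 9 were lower and 1 higher. The median was -0.54 (camera adjusted p = 0.015, but adjusted p = 0.51 with an estimated correlation), and the call was lost without EGFP replicate 1 (adjusted p = 0.092) and without EYFP replicate 2 (adjusted p = 0.078). Lgr5, the receptor that marks crypt stem cells, had a log2 fold change of -1.15 ± 0.31; it was -0.68 without EGFP replicate 1 (adjusted p = 0.19), with adjusted p of 0.057 and 0.12 without EYFP replicates 1 and 2. Slc12a2, a chloride cotransporter, fell by 1.72 ± 0.21. Mecom had a log2 fold change of -1.89 ± 0.40 (-1.14 without EGFP replicate 1), with adjusted p of 0.059 and 0.055 without EYFP replicates 1 and 2. Of 24 enterocyte genes measured, 3 were lower (Fabp2, Enpep and Dgat1), 0 were higher and 21 did not pass, with 0 past the test when adjusted over the list alone. The median was 0.03 while the camera test pointed down (adjusted p = 0.48; without EYFP replicate 2 it was 0.011, and without EYFP replicate 1 the test pointed up at 0.32). Alpi, intestinal alkaline phosphatase, stood at 42.2 ± 10.1 CPM in EGFP and 32.7 ± 16.5 CPM in EYFP. Fabp2, a fatty acid binding protein, and Enpep, an aminopeptidase, had log2 fold changes of -1.43 ± 0.36 and -1.01 ± 0.28. Both calls were lost without either EGFP replicate and without EYFP replicate 1, where the values were -1.02 and -0.70; without EYFP replicate 2 Fabp2 had -2.02.

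**Figure D2:**
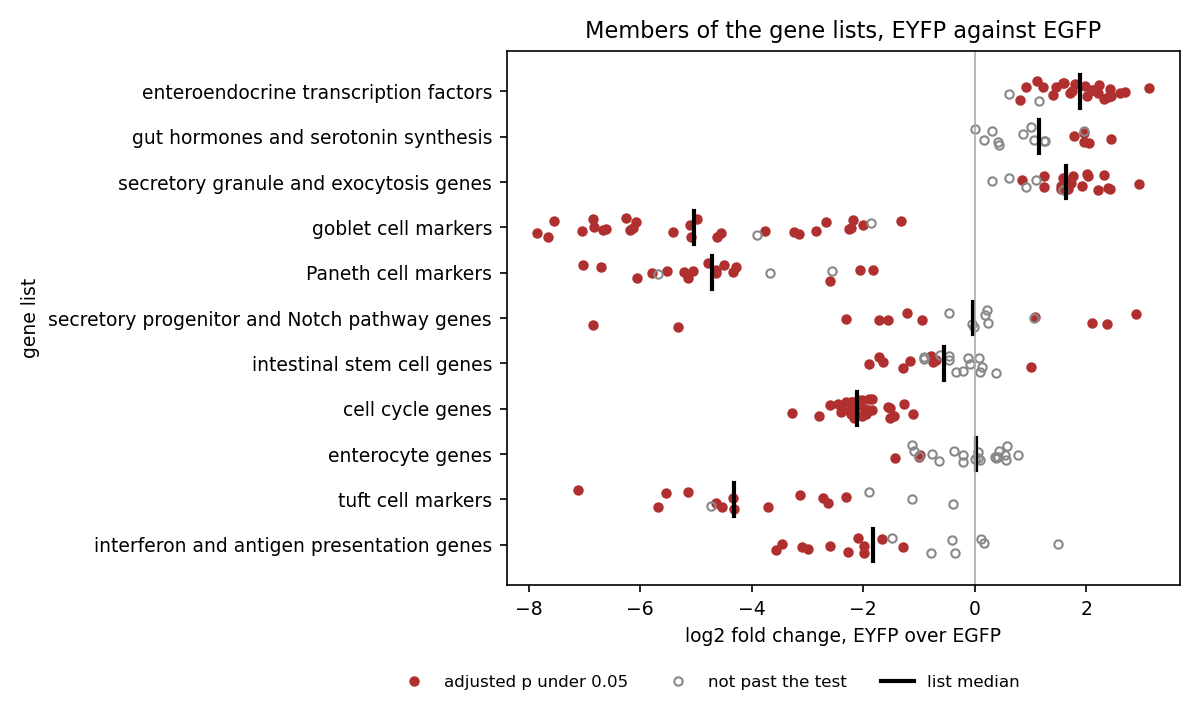
Log2 fold change of EYFP over EGFP for each member of 11 gene lists, filled where the edgeR adjusted p is under 0.05, with a black bar at the list median. Endocrine lists lie to the right of 0, goblet, Paneth, tuft and cell cycle lists to the left, and the enterocyte median lies at 0.03.

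Among the lists for other cell types and states, interferon and antigen presentation genes had 11 of 18 members lower and 0 higher in EYFP cells (11 lower when adjusted over the list alone). Their median was -1.82 (camera adjusted p = 1.6e-05, but adjusted p = 0.37 with an estimated correlation). Zbp1, a sensor of nucleic acids, fell by 3.56 ± 0.32 (log2 fold change -4.18 without EYFP replicate 2), and B2m, the light chain of MHC class I, from 401 and 454 to 166 and 186 CPM. Genes of endoplasmic reticulum folding had 9 of 20 members lower and 0 higher (9 lower when adjusted over the list alone), with a median of -0.51 (camera adjusted p = 0.00076, but adjusted p = 0.51 with an estimated correlation). Edem1, which targets misfolded glycoproteins for degradation, fell by 2.11 ± 0.18. Immediate early genes had 5 of 18 members higher and 0 lower (5 higher when adjusted over the list alone), with a median of 0.80 (camera adjusted p = 0.00041, but adjusted p = 0.51 with an estimated correlation). Btg2 had a log2 fold change of 1.25 ± 0.22, with an adjusted p of 0.051 without EGFP replicate 1. Of 3 neuron and glia markers, 2 were higher by both adjustments, Ret and Elavl4, the latter by 2.81 ± 0.41 (camera adjusted p = 0.03, but adjusted p = 0.37 with an estimated correlation). Both are also known in enteroendocrine cells. Of 7 stromal, endothelial and muscle markers, 3 were higher (Vim, Pecam1 and Myh11) and 0 lower by both adjustments; the median was -0.82 while the camera test pointed up (adjusted p = 0.23). Vimentin (Vim) stood at 171 ± 3.37 CPM in EGFP and 1303 ± 592 CPM in EYFP. The collagen genes Col1a1, Col1a2 and Col3a1 did not pass. Immune cell markers had 1 of 17 higher (Coro1a, log2 fold change 1.67 ± 0.48) and 1 lower (Itgae), with 0 past the test when adjusted over the list alone (camera adjusted p = 0.81). The call of Coro1a was lost without either EGFP replicate and without EYFP replicate 1 (1.18). Proximal small intestine genes had 1 of 10 lower (Cybrd1, -2.70 ± 0.70, lost without any 1 of the 4 libraries compared, adjusted p from 0.06 to 0.12; 0 past the test when adjusted over the list alone; camera adjusted p = 0.57). Distal intestine genes had 2 of 4 lower by both adjustments, Car4 and Guca2b, the latter with a log2 fold change of -2.98 ± 0.47, and -3.64 without EYFP replicate 2 (camera adjusted p = 0.16). Of 2 acinar markers, Rnase1 was lower by both adjustments (-4.57 ± 0.87; adjusted p of 0.091 and 0.064 without EYFP replicates 1 and 2) and Cela1 did not pass (camera adjusted p = 0.44). Rnase1 had -3.35, -5.21 and -5.42 without EGFP replicate 1, EGFP replicate 2 and EYFP replicate 2.

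In total 2343 genes were higher and 2702 lower in EYFP than in EGFP cells at an edgeR adjusted p under 0.05, of which 1488 and 1473 differed by at least 2-fold. The balance depended on the scaling, with 2696 higher and 2423 lower with DESeq2 size factors, and 2646 and 2498 in the DESeq2 Wald test. Outside the lists, among genes without a Gm, Rik or ENSMUSG symbol at 10 CPM or more in both libraries of the higher group, the largest falls were of Ido1 (-9.34 ± 1.04), which degrades tryptophan, A4gnt (-8.59 ± 1.05), which caps O-glycans of mucins, and Slc2a10 (-7.41 ± 0.70), a sugar transporter. The largest rises were of Eno1b (5.16 ± 0.46), Sulf1 (4.12 ± 0.46), a sulfatase that edits heparan sulfate, and C87414 (3.61 ± 0.93). Eno1b and C87414 are uncertain because near-identical copies share their reads. A4gnt held 2 counts over both EYFP libraries, a level 408-fold below EGFP with a 95% counting interval of 112 to 3370, and 255-fold and 186-fold without EGFP replicate 1 and EYFP replicate 1. Without EYFP replicate 2, A4gnt was at least 148-fold and Slc2a10 at least 195-fold lower, and Slc2a10 had a log2 fold change of -6.33 without EYFP replicate 1. Ido1 had -9.95 and -8.1 without EGFP replicates 1 and 2, and without EYFP replicate 2 a level 1220-fold lower (counting interval 336 to 10000). Eno1b had 6.18 and 4.47 without EGFP replicates 1 and 2, and Sulf1 3.53 without EYFP replicate 1. C87414 had 2.8 without EGFP replicate 1, and was at least 46.8-fold higher without EGFP replicate 2. The adjusted p of C87414 was 0.12 and 0.072 without EYFP replicates 1 and 2, and 0.058 and 0.057 without wild-type replicates 1 and 2. The numbers of genes past the test fell to 1138 higher and 1254 lower without EGFP replicate 1. Without EGFP replicate 2, 1474 were higher. They were 1255 and 1482 without EYFP replicate 1, and 1350 and 1582 without EYFP replicate 2. With no filter on low counts, Clca1, Dclk1, Rnase1 and C87414 missed the threshold (adjusted p = 0.06, 0.059, 0.066 and 0.12), and C87414 also with DESeq2 (0.073) or with the 4 libraries compared alone (0.061).

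The comparison of EGFP cells with wild-type epithelium sets the sorted cells with 1 allele beside the epithelium. The sort, the genotype and the reporter differ together in it, and so do the sex-linked transcripts where wild-type replicate 1 is concerned. The gut segment of the sorted cells is not given in the sources used here, and the titles of the wild-type libraries point to duodenum. Neurog3 was 4.59 ± 0.33 higher on the log2 scale (edgeR adjusted p = 8.3e-05). Enteroendocrine transcription factors were higher in 24 of 26 cases, hormones in 14 of 16 and granule genes in 25 of 25, with 0 lower in each list. Adjusted over the list alone, the numbers higher were 25, 14 and 25. Their medians were 4.22, 4.89 (4.54 with Gal and Gast at their bounds) and 4.35, with camera adjusted p of 8e-17, 5.8e-07 and 8e-17, but adjusted p = 0.29, 0.30 and 0.30 with an estimated correlation. Examples are Etv1 (4.98 ± 0.51), ghrelin (Ghrl, 6.02 ± 0.34), Gcg (4.35 ± 0.37), Chga (4.31 ± 0.36) and secretagogin (Scgn, 5.18 ± 0.22). Goblet cell markers were higher as well: 27 of 30 rose and 1, St6galnac1, fell (28 higher and 1 lower when adjusted over the list alone). The median was 3.38 (camera adjusted p = 3.9e-14, but adjusted p = 0.30 with an estimated correlation). The phospholipase gene Pla2g10 rose by 4.32 ± 0.44. Muc2 was 2.96 ± 0.73 higher (edgeR adjusted p = 0.02), but its adjusted p was 0.084 without EGFP replicate 2, 0.15 and 0.13 without wild-type replicates 1 and 2, and 0.11 with no filter on low counts. Secretory progenitor and Notch genes had 10 of 18 higher and 5 lower (11 higher and 6 lower when adjusted over the list alone), with a median of 1.23 (camera adjusted p = 0.023, but adjusted p = 0.30 with an estimated correlation). Atoh1 rose by 3.64 ± 0.31 and Tubb3 by 4.70 ± 0.47 (5.38 without wild-type replicate 1).

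Enterocyte genes were lower in EGFP cells in 24 of 24 cases, also when adjusted over the list alone. The median was -4.52 (camera adjusted p = 2.7e-14, but adjusted p = 0.30 with an estimated correlation). The apolipoprotein gene Apoa4 fell by 6.31 ± 0.54 and Alpi by 5.14 ± 0.41. Immune cell markers were lower in 13 of 17 cases and higher in 0 (13 lower when adjusted over the list alone), with a median of -4.35 (camera adjusted p = 3.4e-06, but adjusted p = 0.30 with an estimated correlation). The T cell receptor subunit Cd3e fell by 5.41 ± 0.50. Proximal small intestine genes had 5 of 10 lower, also when adjusted over the list alone, among them Lct, lactase (-6.10 ± 0.65, and -5.43 without wild-type replicate 2; camera adjusted p = 0.0098, but adjusted p = 0.30 with an estimated correlation). The proximal list shares Lct and Fabp1 with the enterocyte list and Pdx1 with the enteroendocrine factors, so it does not measure gut position apart from cell type. Folding genes of the endoplasmic reticulum had 12 of 20 higher and 0 lower (13 higher when adjusted over the list alone), with Pdia6 1.87 ± 0.23 higher (camera adjusted p = 0.0018, but adjusted p = 0.55 with an estimated correlation). Enterochromaffin genes had 9 of 12 higher and 2 lower, with the same counts when adjusted over the list alone, and Tac1 4.91 ± 0.33 higher (camera adjusted p = 0.0021, but adjusted p = 0.50 with an estimated correlation).

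The remaining lists did not pass the camera test in this comparison. Cell cycle genes had 1 of 30 higher (Plk1, 0.99 ± 0.23, lost without EGFP replicate 2 at 0.068 and without wild-type replicate 2 at 0.073) and 0 lower, with 0 past the test when adjusted over the list alone. Their median was -0.07 while the test pointed up (camera adjusted p = 0.81). Mki67 stood at 340 ± 16.1 CPM in EGFP and 350 ± 115 CPM in wild type. Paneth cell markers had 4 of 20 higher and 2 lower, by both adjustments, with a median of -0.04 (camera adjusted p = 0.87). The log2 fold change of Lyz1 was 0.04 ± 0.39, and Gm14851, a defensin-related gene whose reads are shared, had -3.91 ± 0.55 (-4.65 without EGFP replicate 1). Stem cell genes had 5 of 22 higher and 3 lower by both adjustments (camera adjusted p = 0.38); Lgr5 had -0.08 ± 0.30, and Sp5 -2.52 ± 0.59 (adjusted p = 0.068 without wild-type replicate 2; -3.81 and -1.75 without EGFP replicates 1 and 2). Tuft cell markers had 2 of 17 higher and 1 lower by both adjustments (camera adjusted p = 0.13). Dclk1 had 1.3 ± 0.69, and 2.72 without wild-type replicate 2 (adjusted p = 0.013). Gng13 had 2.94 ± 0.79, a call lost without any 1 of the 4 libraries (adjusted p from 0.064 to 0.15) and with DESeq2 (0.071). Without wild-type replicate 2 its level was 16.1-fold higher, with a 95% counting interval of 2.66 to 660. Interferon and antigen presentation genes had 1 of 18 higher (Oas2) and 6 lower, 3 and 6 when adjusted over the list alone (camera adjusted p = 0.20); H2-Q1, from a family of similar genes, fell by 3.09 ± 0.30 on the log2 scale. Neuron and glia markers had 2 of 3 higher by both adjustments, with Ret at 4.03 ± 0.31, and lay just above the threshold (camera adjusted p = 0.05). Stromal, endothelial and muscle markers had 2 of 7 higher, Pecam1 and Vim (3.70 ± 0.33), and 1 when adjusted over the list alone (camera adjusted p = 0.24). Immediate early genes had 1 of 18 higher (Dusp1) and 2 lower (Zfp36 and Klf6), 1 and 1 when adjusted over the list alone (camera adjusted p = 0.42). Klf6 had -1.16 ± 0.34, lost without either EGFP replicate and without wild-type replicate 1 (-0.81). Distal intestine genes had 1 of 4 higher and 2 lower by both adjustments (camera adjusted p = 0.29). Hoxb8, at 0 in wild type, was at least 8.53-fold higher, a call lost without any 1 of the 4 libraries (adjusted p from 0.059 to 0.085), with a bound of 4.95 and 3.58 without wild-type replicates 1 and 2. Neither acinar marker passed (camera adjusted p = 0.88).

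Over all genes, 2733 were higher and 3046 lower in EGFP cells than in wild type, 2887 and 2885 with DESeq2 size factors, and 2828 and 2923 in the DESeq2 Wald test. Outside the lists and under the same limits of symbol and CPM, the largest rises were of Ceacam2 (8.08 ± 0.43), Ear2 (6.86 ± 0.59) and Nefl (6.60 ± 0.50), a neurofilament gene. The largest falls were of Aqp8 (-7.54 ± 0.89), a water channel, and of the cytochrome P450 genes Cyp2c29 (-7.39 ± 0.84) and Cyp2c55 (-7.37 ± 0.26). Ceacam2, Ear2 and the Cyp2c genes belong to families of similar genes, and their values are uncertain. Several of these folds rest on few counts. Nefl held 3 counts over both wild-type libraries, a level 105-fold below EGFP (95% counting interval 35.5 to 514; 183-fold and 66.3-fold without wild-type replicates 1 and 2). Ear2 was 211-fold higher without wild-type replicate 2 (counting interval 37.7 to 8370). Cyp2c29 held 3 counts over both EGFP libraries, a level 178-fold below wild type (counting interval 60.6 to 864). It was at least 105-fold lower without EGFP replicate 1 and 73.3-fold lower without EGFP replicate 2. Aqp8 had -6.69 without EGFP replicate 1 and was at least 125-fold lower without EGFP replicate 2. The number of genes lower was 1820 without EGFP replicate 1.

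The comparison of EYFP cells with wild-type epithelium sets the sorted cells with 2 alleles beside the epithelium. The sort, the reporter and the strain label differ together in it, and so do the sex-linked transcripts where wild-type replicate 2 is concerned. Neurog3 was 6.20 ± 0.35 higher on the log2 scale (edgeR adjusted p = 1.3e-05). Enteroendocrine transcription factors were higher in 25 of 26 cases, hormones in 15 of 16 and granule genes in 25 of 25, with 0 lower. Adjusted over the list alone, the numbers higher were 26, 15 and 25. Medians were 6.25, 5.78 (5.73 with Gal and Gast at their bounds) and 6.03, with camera adjusted p of 3.1e-16, 7.3e-08 and 1.5e-15, but adjusted p = 0.30, 0.41 and 0.41 with an estimated correlation. Fev, a factor of serotonin-producing cells, rose by 7.08 ± 0.43, Rab3c by 7.33 ± 0.42, Chga by 6.23 ± 0.39 and Gcg by 6.14 ± 0.40. The neuropeptide galanin (Gal), at 0 in wild type, was at least 18.6-fold higher. The bound was 10.4 without EYFP replicate 1, and 10.8 and 7.83 without wild-type replicates 1 and 2. Enterochromaffin genes had 10 of 12 higher and 2 lower by both adjustments, with Tac1 7.36 ± 0.37 higher (camera adjusted p = 0.00023, but adjusted p = 0.43 with an estimated correlation). The 3 neuron and glia markers were all higher by both adjustments, with Elavl4 at 6.31 ± 0.55 (camera adjusted p = 0.019, but adjusted p = 0.41 with an estimated correlation). Elavl4 held 3 counts over both wild-type libraries, a level 86.6-fold below EYFP with a 95% counting interval of 29.3 to 423.

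Paneth cell markers were lower than in wild type in 17 of 20 cases and higher in 0, by both adjustments. The median was -5.00 (camera adjusted p = 4.6e-07, but adjusted p = 0.41 with an estimated correlation), with Lyz1 at -4.24 ± 0.45 and Mptx2 at -6.82 ± 0.81. All 30 cell cycle genes were lower by both adjustments, with a median of -2.20 (camera adjusted p = 2.3e-09, but adjusted p = 0.46 with an estimated correlation). Mki67 fell by 2.26 ± 0.31 and the mitotic checkpoint kinase Bub1 by 2.75 ± 0.33. All 24 enterocyte genes were lower by both adjustments, with a median of -4.81 (camera adjusted p = 1.3e-09, but adjusted p = 0.43 with an estimated correlation). Alpi fell by 5.52 ± 0.41 and the glucose transporter gene Slc2a2 fell by 7.05 ± 0.78. Tuft cell markers were lower in 10 of 17 cases and higher in 0 by both adjustments, with a median of -3.24, or -3.16 with Gng13 at its bound (camera adjusted p = 0.01, but adjusted p = 0.64 with an estimated correlation). Dclk1 had -3.24 ± 0.85 (adjusted p of 0.11 and 0.061 without EYFP replicates 1 and 2). Alox5 had -4.83 ± 1.33 (adjusted p of 0.13 and 0.08 without the same libraries), and -2.52 without wild-type replicate 2 (adjusted p = 0.056). With no filter on low counts, Dclk1 and Alox5 missed the threshold (0.086 for each). Immune markers were lower in 13 of 17 cases (14 when adjusted over the list alone) and interferon and antigen presentation genes in 14 of 18 (15 when adjusted over the list alone), the latter with 1 higher, Usp18. Camera gave adjusted p = 0.00017 and 0.00023, but adjusted p = 0.41 and 0.41 with an estimated correlation. Cd3e fell by 5.57 ± 0.49 and Ifit1 by 4.39 ± 0.61. Without EYFP replicates 1 and 2, Ifit1 had -3.63 and -5.81 and Mptx2 -6.21 and -7.74, while Lyz1 had -4.93 without the first and Alpi -6.15 and Dclk1 -3.9 without the second. Alox5 had -4.07 without EYFP replicate 1, and a level 91.3-fold lower without EYFP replicate 2 (95% counting interval 16.2 to 3630). Without wild-type replicates 1 and 2, Slc2a2 had -7.64 and -6.08 and Dclk1 -3.92 and -1.82, while Alox5 had -5.66 without the first and Mptx2 -5.95 without the second.

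Goblet cell markers were split in this comparison, with 16 of 30 lower, 5 higher and 9 not past the test by both adjustments; the median was -1.49 (camera adjusted p = 0.076). Muc2 fell by 4.59 ± 0.79 on the log2 scale (log2 fold changes of -3.83 and -6.23 without EYFP replicates 1 and 2). The higher members were Qsox1, Txndc5, Galnt12, Creb3l1 and Foxa3. Secretory progenitor and Notch genes had 9 of 18 higher and 7 lower by both adjustments (camera adjusted p = 0.40). Atoh1 fell by 1.68 ± 0.33 and Tubb3 rose by 7.08 ± 0.46 (7.74 without wild-type replicate 1). Stem cell genes had 4 of 22 higher and 11 lower by both adjustments (camera adjusted p = 0.39). Lgr5 had -1.24 ± 0.31 (adjusted p = 0.058 without EYFP replicate 2 and 0.05 without wild-type replicate 1), and Sp5 -2.43 ± 0.58 (adjusted p = 0.058 without EYFP replicate 1). Immediate early genes had 5 of 18 higher (3 when adjusted over the list alone), with Dusp1 1.80 ± 0.17 higher (camera adjusted p = 0.063). Folding genes had 2 of 20 higher and 1 lower (Edem1, -1.91 ± 0.18), 0 and 1 when adjusted over the list alone (camera adjusted p = 0.51). Proximal genes had 6 of 10 lower by both adjustments, with Lct at -6.31 ± 0.66, -7.05 without EYFP replicate 2 and -5.64 without wild-type replicate 2 (camera adjusted p = 0.089). Lct is also a member of the enterocyte list. Distal genes had 1 of 4 higher and 2 lower by both adjustments (camera adjusted p = 0.30). Hoxb8 was at least 8.77-fold higher, a call lost without EYFP replicate 1 (adjusted p = 0.083) and without wild-type replicate 2 (0.057). Without EYFP replicate 1 only 3 counts were left, which is the floor and gives no bound. The bound was 14.1 without EYFP replicate 2, and 5.09 and 3.68 without wild-type replicates 1 and 2. Stromal, endothelial and muscle markers had 3 of 7 higher by both adjustments, with Vim at 6.63 ± 0.38; the median was -0.68 while the test pointed up (camera adjusted p = 0.17). Of the acinar markers, Rnase1 had -3.43 ± 0.84 (-4.27 without EYFP replicate 2), lost without EYFP replicate 1 (0.10), EYFP replicate 2 (0.056) or wild-type replicate 2 (0.084) and with no filter on low counts (0.079; camera adjusted p = 0.51).

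**Figure D3:**
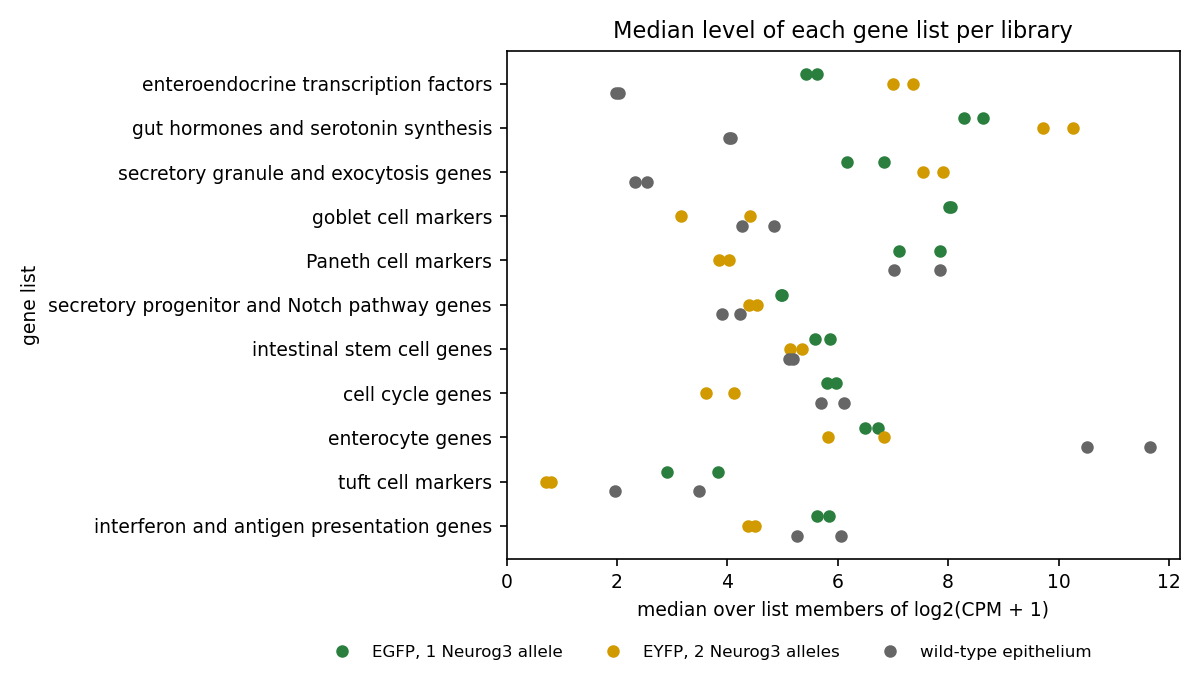
Median over the members of each gene list of log2(CPM + 1), with 1 point per library and colours for the 3 groups. Goblet markers are highest in the EGFP libraries, cell cycle genes lie lower in the EYFP libraries than in the others, and both sorts lie far below wild type for enterocyte genes.

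Over all genes, 3778 were higher and 4668 lower in EYFP cells than in wild type, 4173 and 4183 with DESeq2 size factors, and 4078 and 4157 in the DESeq2 Wald test. The median log2 fold change of all tested genes was -0.12 in this comparison and -0.01 with DESeq2 size factors. Outside the lists and under the same limits of symbol and CPM, the largest rises were of the glutamate receptor gene Grin2c (8.59 ± 0.58), the GABA receptor gene Gabra2 (8.42 ± 0.58) and Ccdc154 (7.94 ± 0.58). The largest falls were of AA467197 (-7.39 ± 1.5), Cyp2c29 (-7.36 ± 0.80) and Sprr2a2 (-7.33 ± 1.03). Cyp2c29 and Sprr2a2 have similar copies and are uncertain, and the adjusted p of AA467197 was 0.11 and 0.12 without EYFP replicates 1 and 2. AA467197 stood at 19.9 and 162 CPM in the wild-type libraries and had -8.04 without EYFP replicate 1. Without wild-type replicates 1 and 2, AA467197 had -8.22 and -5.2 and Sprr2a2 -8.02 and -5.96. Cyp2c29 had -6.28 without EYFP replicate 1 and was at least 125-fold lower without EYFP replicate 2. The leading rises rest on few wild-type counts: Grin2c held 3 and Gabra2 and Ccdc154 1 each over both libraries. Their levels in EYFP were 426-fold, 434-fold and 311-fold higher, with 95% counting intervals of 145 to 2070, 77.5 to 17200 and 55.4 to 12300. The levels were 247-fold, 252-fold and 181-fold higher without wild-type replicate 1, and at least 179-fold, 60.8-fold and 43.6-fold higher without wild-type replicate 2.

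Both sorted groups were compared with the same wild-type libraries, so their fold changes share chance values. Of the genes past the test in both comparisons, 2192 were higher in both and 2630 lower in both. In 20 simulations, all 6 libraries were drawn anew from the wild-type mean levels, so that no gene was changed. At most 2 genes were then higher in both and at most 2 lower in both. Few calls were due there in any case, so these counts do not show what sharing adds where genes do change. Independent lists of the observed sizes would share 741 and 1020. The correlation of fold changes across genes was 0.838, against 0.463 in the simulations. The covariance was 3.31 against 0.148. With 2 wild-type libraries, a split of the controls would leave 1 for each sort and was not made, and part of the excess may come from sharing them.

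The authors' deposited table of comparisons covers 14631 genes. It calls 5082 genes between EGFP and EYFP cells, 4845 between EGFP cells and wild type, and 7619 between EYFP cells and wild type at an adjusted p under 0.05. Of these, 4602, 4709 and 7303 were also past the edgeR test, each in the same direction. For Neurog3 the authors' deposited table gives 3.03-fold more in EYFP than in EGFP cells.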

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

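All tests in this part were chosen only after the results were seen. A group of 146 genes stood above wild type in EGFP cells and below it in EYFP cells, with each difference, including that between the sorts, past the edgeR test. It held 14 goblet, 4 Paneth and 1 tuft cell marker, and 22 genes of any list. The number of such genes was 88 without EGFP replicate 1, 95 without wild-type replicate 2 and 109 to 122 without each of the other libraries. Of the 146 genes, 59 still passed each test under all 6 of these omissions, 11 goblet and 2 Paneth cell markers among them. Examples are the goblet factor Spdef (log2 fold changes over wild type of 3.54 in EGFP and -3.12 in EYFP), the mucus protein gene Fcgbp (3.72 and -2.46) and, outside the lists, the potassium channel gene Kcnk6 (3.64 and -2.85). The reverse held for 14 genes, none of them in a list. Without 1 library the number was 5 to 15, and 0 of the 14 still passed each test under all 6 of these omissions.

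As a source of the excess of goblet genes in EGFP cells, unselected cells like those of the wild-type libraries could not raise these transcripts above those libraries, and the median of the list was 3.38 above them (quartiles 3.09 and 3.71), which argues against such cells. Unselected cells of another gut segment remain open, since the segment of the sort is not given in the sources used here. Hox genes, which mark position along the gut, had a median of 2.29 over wild type (4 of 8 higher, 0 lower, camera adjusted p = 0.019, but adjusted p = 0.66 with an estimated correlation). They cannot decide, since endocrine cells of that segment would show the same. EYFP cells, without the goblet excess, had a Hox median of 2.88 over wild type (6 of 8 higher, 0 lower), and 0 passed between the sorts. Enterocyte genes, also part of unselected epithelium, were lower than wild type in 24 of 24 cases in EGFP cells (median -4.52). Their level in another segment was not measured. The EGFP and wild-type libraries are both labelled C57BL6, which argues against strain as the whole cause of the goblet excess over wild type. The 27 of 30 markers higher in EGFP than in wild type are that excess itself and add no test of strain. For the difference between EGFP and EYFP cells, whose strain labels differ, strain stays open. Goblet cells caught in the EGFP sort remain open. The median of the secretory-lineage factors Atoh1 and Gfi1 and the goblet factor Spdef was 3.54 above wild type, with Muc2 at 4179 and 5144 CPM. Reporter-positive cells on the way to a goblet fate could give the same values. The labels' Neurog3 alleles, strain and reporter and the sex-linked transcripts all differ between EGFP and EYFP cells, the gates are not given in the sources used here, and a biological difference in dose was not tested apart from them.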

How the results depend on the processing

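The test against a fold of 2 and the test of autosomal genes were chosen only after the results were seen. No result past the test, in the analysis as reported or in the alternative, changed direction. Directions of results that did not pass changed in 10 cases. The enterocyte list between the sorts pointed up without EYFP replicate 1 (adjusted p = 0.32), where Alpi had a log2 fold change of 0.07 (lowest -1.02, without EYFP replicate 2). Between EGFP and wild type, Lgr5 had 0.26 without EGFP replicate 2 and 0.16 without wild-type replicate 1 (lowest -0.41, without EGFP replicate 1). Lyz1 had -0.21 without EGFP replicate 2 and -0.11 without wild-type replicate 2 (highest 0.36, without EGFP replicate 1). Mki67 had 0, 0.01 and 0.34 without EGFP replicate 1, EGFP replicate 2 and wild-type replicate 1 (lowest -0.34, without wild-type replicate 2), and 0.03 in the 4 libraries compared alone; the cause was not tested. Of 96 recomputed gene counts, 78 stayed within 1.5 times; of 170 list tests, which cover 10 lists between the sorts and, with an estimated correlation, all lists, 128 kept their direction and side of the threshold, 39 lost their call and 2 gained one; of 1479 values of named genes, 1389 kept both, 80 lost their call and 1 gained one. DESeq2 size factors gave 52.7% of the calls between the sorts as higher, against 46.4% with TMM. The gene counts that moved did so under fold thresholds or with fewer libraries. With a fold of at least 2, 1488 genes were higher and 1473 lower in EYFP than in EGFP, 1810 were lower in EGFP than in wild type and 3087 were lower in EYFP than in wild type. The edgeR test against a fold of 2 called 461 higher and 648 lower, 1356 and 1120, and 2212 and 2199 in the 3 comparisons, and changed 35 of 120 counts of list members by over 1.5 times. Autosomal genes alone gave 2246 and 2573, 2606 and 2947, and 3611 and 4461.

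Leaving out 1 library at a time gave 1138 to 2525 genes higher and 1254 to 2958 lower in EYFP than in EGFP, 1937 to 2494 higher and 1820 to 3019 lower in EGFP than in wild type, and 3139 to 4224 higher and 3707 to 4498 lower in EYFP than in wild type. The log2 fold change of Neurog3 between the sorts ranged from 1.22 to 1.93 and stayed past the test. Of the 43, 31 and 35 named genes past the test, 14, 6 and 7 lost their call without some library. Camera adjusted p between the sorts ranged from 2.6e-14 to 3.9e-13 for enteroendocrine factors, 1.9e-06 to 0.066 for hormones, 2.1e-13 to 1.4e-09 for granule genes, 1.2e-24 to 1.3e-17 for goblet, 2.1e-13 to 6.4e-12 for Paneth, 0.27 to 0.49 for Notch, 0.0011 to 0.092 for stem, 4.1e-19 to 3.3e-16 for cell cycle, 0.011 to 0.82 for enterocyte and 4.8e-08 to 2e-06 for tuft genes. The hormone call was lost without EYFP replicate 2 (0.066), the stem call without EGFP replicate 1 (0.092) or EYFP replicate 2 (0.078), and an enterocyte call was gained without EYFP replicate 2 (0.011). Fewer libraries leave fewer degrees of freedom.

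With an estimated correlation, the camera calls of 34 lists were lost, and no list passed in any comparison (lowest camera adjusted p = 0.29). The correlation is estimated from 3 residual degrees of freedom. Calls were lost even where the estimate was under the preset 0.01, at -0.36 for neuron and -0.05 for Notch genes. A lost call here therefore does not show that the genes of a list vary together, and the cause was not tested further. Between the sorts the adjusted p was 0.37 for enteroendocrine factors, granule, goblet, Paneth, cell cycle, neuron and interferon genes, 0.42 for tuft and enterochromaffin, 0.49 for hormones and 0.51 for stem, immediate early and folding genes. For EGFP against wild type it was 0.29 for enteroendocrine factors, 0.3 for hormones, granule, goblet, Notch, enterocyte, proximal and immune genes, 0.5 for enterochromaffin and 0.55 for folding genes. For EYFP against wild type it was 0.3 for enteroendocrine factors, 0.41 for hormones, granule, Paneth, immune, neuron and interferon genes, 0.43 for enterocyte and enterochromaffin, 0.46 for cell cycle and 0.64 for tuft genes. With fry between the sorts, hormones (0.14), stem (0.094), immediate early (0.097) and folding genes (0.067) lost their call, and Notch (0.0024), distal (0.04) and acinar genes (0.025) gained one; the cause was not tested. Against wild type, fry called 12 lists in EGFP and 14 in EYFP, where camera called 10 and 11. The replicate numbers did not pair the samples (correlations of deviations 0.02, 0.1 and 0.01). The replicate block gave 2512 and 2932, 2814 and 3155, and 3850 and 4780 genes higher and lower, changed none of the calls of the 10 lists retested with it, all between the sorts, and lost 4 calls of named genes: C87414 (0.065) and Rnase1 (0.071) between the sorts, Klf6 (0.052) between EGFP and wild type, and Rnase1 (0.081) between EYFP and wild type.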

Other observations

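All tests in this part were chosen only after the results were seen. Among 26 gene families picked by symbol, voltage-gated and TRP ion channels, which set the excitability of endocrine cells, had 33 of 79 genes higher and 11 lower in EYFP than in EGFP cells (median log2 fold change 1.2, camera adjusted p = 0.00091, but adjusted p = 0.66 with an estimated correlation). The sodium channel gene Scn3a stood at 63.9 and 86.1 CPM in EGFP and 520 and 401 CPM in EYFP (2.62 ± 0.22), and Trpc7 rose by 2.85 ± 0.28. The potassium channel gene Kcnk6 fell by 6.49 ± 0.28, but its channel is not voltage-gated, and a family picked by symbol can hold such genes. Glycosyltransferases of O-glycans, which build mucin sugars, had 20 of 46 genes lower and 3 higher (Gcnt4, Galnt11 and St6galnac2), with a median of -0.62 (camera adjusted p = 0.0032, but adjusted p = 0.66 with an estimated correlation). Galnt5 fell by 6.05 ± 0.57 (log2 fold changes of -5.22 and -7.69 without EYFP replicates 1 and 2) and Fut4 fell by 2.61 on the log2 scale.

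Cytosolic ribosomal protein genes had 55 of 77 members lower and 0 higher in EYFP than in EGFP cells, with a median of -0.67 (camera adjusted p = 1.5e-12, but adjusted p = 0.68 with an estimated correlation). Rpl12 stood at 781 and 693 CPM in EGFP and 316 and 336 CPM in EYFP, with an adjusted p of 0.055 without EGFP replicate 1. Respiratory chain and ATP synthase genes had 46 of 82 lower and 1 higher, Cox7a2l (median -0.5, camera adjusted p = 7.4e-10, but adjusted p = 0.66 with an estimated correlation). Against wild type, 70 of the 82 were lower in EGFP cells (median -0.91, camera adjusted p = 9.6e-17, but adjusted p = 0.59 with an estimated correlation). These medians kept their sign under both other scalings.

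The rise of enteroendocrine genes in EYFP cells was weighed against dilution of the same endocrine cells by other cells in the EGFP sort, where a single factor would lower genes restricted to endocrine cells alike. Of 46 members of the 3 endocrine lists at a log2 fold change of at least 4 in EGFP over wild type, 14 lay over 2 SE from their median difference of 1.69, where the estimated error alone gives 3.76. The excess had a binomial p of 1.15e-05, which takes the genes as independent. Since the estimated error may hold no variation between separate preparations, the count does not decide, whatever its size. Dilution remains open as a part or the whole of the difference. The same holds for Neurog3 itself, whose log2 fold change of 1.61 ± 0.28 between the sorts lies near the median of 1.69. Neurog3 is 1 of the 46 members, so this nearness is no separate evidence. The sex of the mice stays open, since the wild-type library with high Y-linked transcripts exceeded the other by 0.11 in the median factor and there is 1 library of each kind. Neurog3 dose stays an untested hypothesis, as it cannot be told apart from strain and reporter here.

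The fall of interferon and antigen presentation genes in EYFP cells was weighed in the same way. Strain variants of H2 genes are argued against by the other 15 members, whose median was -1.99 (quartiles -2.8 and -1.38), against 0.113 for the 3 H2 members. Leukocytes in the EGFP sort are argued against by the immune markers, whose median was -0.15 (quartiles -0.777 and 0.812). The sex of the mice stays open, with a difference of -0.46 between the wild-type libraries of either pattern. Strain in other respects, reporter and Neurog3 dose could each contribute and were not tested apart. The sorts also differed in goblet, Paneth, tuft and cell cycle genes, with medians of -5.04, -4.71, -4.32 and -2.11 in EYFP over EGFP. Over wild type, the interferon list had a median of -0.39 in EGFP and -2.11 in EYFP cells. Whether its fall goes with the cell make-up of the sorts was not tested.

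At a minimum of 3 CPM in both EYFP libraries, 2 genes were at 0 in the other 4 libraries, Gm8801 on chromosome 17 (5.36 and 5.13 CPM) and Gm8615 on chromosome 5 (7.96 and 5.72 CPM).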
